A study of Danio rerio with 6 samples.

How the data were processed

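Endothelial cells were sorted from the tails of zebrafish larvae, and their RNA was sequenced. Tg(flk:GFP) larvae carry green fluorescent protein under the promoter of flk, a vascular endothelial growth factor receptor gene, so that blood vessel cells fluoresce. Per the labels' protocols, larvae were injected with phosphate-buffered saline (PBS) or with extracellular vesicles (EVs) from MV4-11 cells, and tails were collected 24 h later. MV4-11 is a human acute myeloid leukaemia cell line, and EVs are small membrane-bound particles that cells release. Tails were dissociated in trypsin, and about 100000 GFP-positive cells per sort went into RNA extraction. A low-input protocol with 15 cycles of amplification and 150 bp paired-end sequencing followed. The 6 libraries fall into 2 groups of 3 by their titles. The labels say that 3 replicates were prepared for each treatment but not whether these were separate pools of larvae or separate days. The p-values therefore measure the spread between these libraries, which may be technical in part.

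The values are the authors' deposited estimated counts, 1 column per library, for 57192 Ensembl transcripts. They were not normalised and not summed to genes. Per the submitters' processing notes, Trim Galore 0.5.0, Salmon 0.03.1 and edgeR 3.40.1 were used with genome build GRCz11. The role and order of these tools and the annotation release are not given in the sources used here. Between 58.9% and 68.8% of the non-zero values per library were not whole numbers, taken exactly as deposited with no tolerance here and in all later counts of whole values, as arises when a read matching several transcripts is divided among them. Transcripts of 1 gene that share sequence are then not measured independently, and a single transcript's value can change without a change in its gene. Values were rounded before testing, which set 143 non-zero values below 0.5 to 0.

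The deposited table gives transcript identifiers alone. Of the 57192 identifiers, 0 matched the gene name table and 0 matched the RefSeq gene table used here. The former holds gene identifiers and the latter had no Ensembl identifiers filled in, so no match was possible. The lack of matches is a limit of these reference tables and not of the deposited identifiers. With them, no transcript could be tied to a gene symbol, a gene or a position. The 32 lists fixed before the data were examined (20 pathway lists and 12 lists of cell type markers) were not tested for this reason, and the endothelial markers that were to be reported in every library, kdrl among them, were not analysed here. The rule for named genes asked for genes with a symbol and, if none passed the test, those with the smallest p. It was applied to transcripts, and the 2 with the smallest p in each direction are given by identifier.

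Of the 39325 transcripts with a count in any library, 18959 passed edgeR's filterByExpr and were tested. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM scaling and Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered a model with the group as its term. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives, as were other scalings, filters, thinning to the smallest library, each library left out in turn, and a replicate block. Standard errors of log2 fold changes were taken as the size of the fitted change over the square root of its F statistic. Comparisons of 1 value per library used exact permutation tests, two-sided unless stated, which cannot go below p = 0.1 with 3 libraries against 3 or below p = 0.25 with 3 pairs. To compare detection, every library was thinned at random to 10393841 counts.

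Both groups carry the replicate numbers 1, 2 and 3 in their titles, and nothing in the labels says what a number marks. Whether libraries of 1 number deviated together was checked from the data. The correlation of deviations from the group means was 0.15 for number 1, 0.26 for number 2 and 0.26 for number 3. All other combinations lay between -0.21 and 0.02. Deviations from a group mean cancel out within the group, so positive values for the same numbers force lower values elsewhere. Few ways exist to match 3 libraries with 3, and chance could also give this matching. Some comparisons below treat the numbers as pairing the libraries on the ground of these correlations, an assumption that the check cannot settle. The main test, its standard errors and dispersion, and the simulation leave the numbers out. Because the pairing was read from the same libraries, comparisons that use it are not independent support for a difference between the groups. Fits with the replicate number as a block, which leave 2 residual degrees of freedom in place of 4, are given beside the main result.

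The tests were tried on simulated counts with the means, library sizes and dispersions of the real transcripts, for the comparison of EV with PBS. After the filter, 16707 transcripts were tested. The edgeR test recovered 0 of 46 transcripts changed 2-fold, 0 of 48 changed 4-fold, 0 of 45 changed 8-fold and 4 of 39 changed 16-fold, and it called 0 of 16529 unchanged transcripts. DESeq2 recovered 1, 7, 17 and 23 of these same sets, and it also called 85 of the 16529 unchanged transcripts. Limma-voom recovered 3 of the 39 transcripts changed 16-fold, 0 of the smaller changes and called 0 unchanged transcripts. The median fitted log2 change in edgeR was 1.01 for the 2-fold set and 4.06 for the 16-fold set. The sets hold only the changed transcripts that passed the filter. With 16529 of the 16707 tested transcripts unchanged, the recovery cannot be carried over to data in which more transcripts change.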

Results

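The transcriptome of endothelial cells sorted from the larval tail was compared between 3 libraries from larvae injected with MV4-11 EVs and 3 libraries from PBS-injected larvae. The comparison addresses which transcripts differ in tail endothelium 24 h after injection of vesicles from a leukaemia cell line. Total estimated counts were 24332767, 17350094 and 18635179 in PBS replicates 1, 2 and 3. They were 18806442, 10393944 and 14880499 in EV replicates 1, 2 and 3. The mean was 20106013 ± 3716443 in PBS and 14693628 ± 4209361 in EV (SD, n = 3 each), with p = 0.3 in an exact permutation test that ignores the replicate numbers. Within each of the 3 same-numbered pairs the EV total was the lower one. EV minus PBS was -5412385 ± 1603773 counts (SD, 3 pairs), with p = 0.25 in an exact sign-flip permutation test, the smallest value that 3 pairs allow. Of the 57192 transcripts listed, 31.2% had no count in any library.

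Whether libraries of a group were more alike than libraries of different groups depended on the treatment of the same-numbered pairs. The Pearson correlation of log2 CPM across the 18959 tested transcripts, which are not independent replicates, averaged 0.67 within PBS, 0.83 within EV and 0.75 between the groups. The mean within groups minus the mean between groups was -0.00392, and 6 of the 10 ways to split the libraries into 3 and 3 gave a value as large (exact permutation test, one-sided, p = 0.6). With the mean within PBS and the mean within EV weighted equally, it was -0.0128, 0.0118 and -0.0107 without PBS replicate 1, 2 and 3, and -0.0145, -0.0142 and 0.017 without EV replicate 1, 2 and 3. Its sign thus turned without PBS replicate 2 and without EV replicate 3. The mean between groups also holds the 3 same-numbered pairs, with correlations of 0.82, 0.87 and 0.68. Without these pairs it was 0.73, against 0.75 within groups, a difference of 0.0154. The other 3 splits that part all same-numbered pairs gave -0.0099, -0.006 and 0.0005. The real split was thus the highest of 4, and 4 splits cannot give a share under 0.25. The pairing was itself read from these libraries. Across groups, each PBS library correlated most with the EV library of its number, so leaving these pairs out lowered the mean between groups. The difference of 0.0154 is therefore not independent evidence that the groups differ. PBS replicate 3 stood apart from the rest. Its mean correlation with the other 5 libraries was 0.63, and the other libraries had means between 0.75 and 0.80. The first principal component held 45.9% of the variance and placed PBS replicate 3 at 270.1, with the other 5 libraries between -78.8 and 1.93. The variation between libraries of 1 group, as edgeR's common dispersion, amounted to a coefficient of variation of 93.3%.

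**Figure D1:**
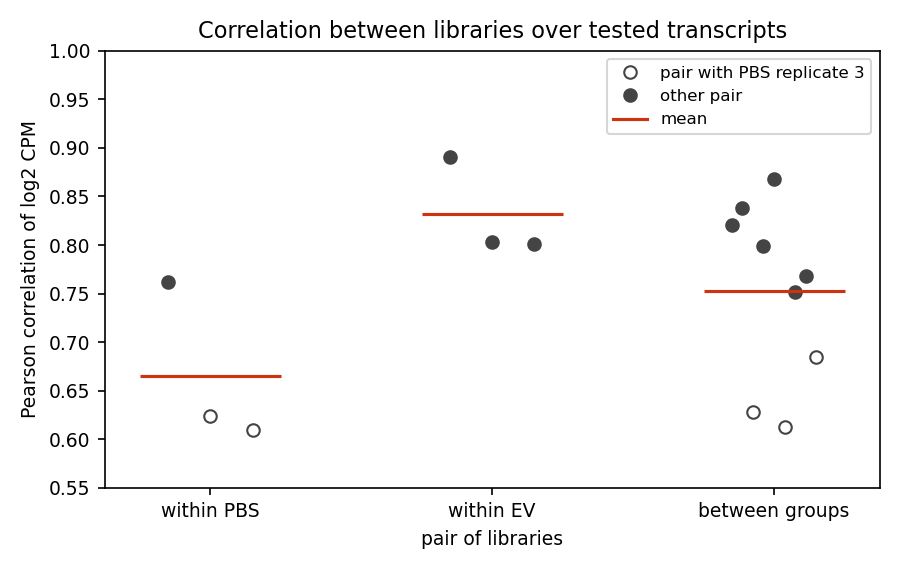
Pearson correlation of log2 CPM (vertical axis) for each pair of the 6 libraries, by kind of pair (horizontal axis). Points are pairs, open where PBS replicate 3 is a member, and lines are the means of 0.67 within PBS, 0.83 within EV and 0.75 between the groups.

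The EV libraries held more kinds of transcripts than the PBS libraries at equal depth. After thinning to 10393841 counts each, 27000 ± 1234 transcripts had at least 1 count in EV and 23391 ± 1863 in PBS (SD, n = 3 each). All 3 EV libraries lay above all 3 PBS libraries, with 25641 in the lowest EV library and 25511 in the highest PBS library. With a minimum of 2 counts these were 22922 and 22819. These narrow gaps come from a single random thinning, which was not repeated. The exact permutation test gave p = 0.1, the smallest value this design allows. As unpaired groups they overlapped at higher minimum counts. With a minimum of 5 counts the lowest EV library had 18682 transcripts and the highest PBS library 18944, and with a minimum of 10 counts these were 15824 and 16722. Each EV library held more transcripts than the PBS library of the same replicate number at every minimum tried (1, 2, 5 and 10 counts). The paired difference was 3610 ± 1476 at a minimum of 1, 2425 ± 1007 at 5 and 1716 ± 1401 at 10 (SD, 3 pairs). An exact sign-flip permutation test of 3 pairs gave p = 0.25 at each minimum, the smallest value it can give. The 10 most abundant transcripts took 19.1% ± 8.43 of all counts in PBS and 16.6% ± 3.17 in EV (SD, n = 3 each; exact permutation test, p = 0.8). The higher PBS mean rests on PBS replicate 3, with 28.85% against 14.66% and 13.87% in PBS replicates 1 and 2. In EV replicates 1, 2 and 3 the share was 19.09%, 13.01% and 17.58%.

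**Figure D2:**
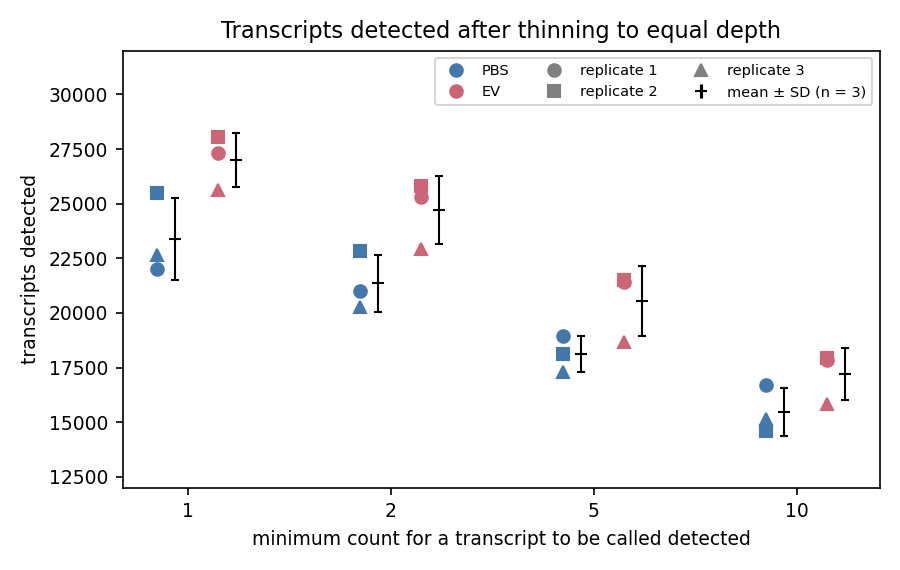
Number of transcripts detected per library after thinning to equal depth (vertical axis, which does not start at 0), for minimum counts of 1, 2, 5 and 10 (horizontal axis). Symbols are libraries by group and replicate, and bars are mean ± SD of 3 libraries. At a minimum of 1 the EV libraries lie above the PBS libraries, and at 5 and 10 the groups overlap, with each EV library above the PBS library of the same number.

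No transcript differed between EV and PBS endothelial cells past the threshold in the main test. The edgeR quasi-likelihood test called 0 of 18959 transcripts at an adjusted p of 0.05, and the smallest adjusted p was 0.243. At an unadjusted p under 0.05 there were 547 transcripts, of which 173 were higher and 374 lower in EV. Chance alone gives about 948 at that level for independent libraries. The direction of this split depended on the scaling, since with library totals alone 281 were higher and 135 lower in EV, and the median log2 change of all tested transcripts moved by 0.43, from -0.20 to 0.23. With the replicate number as a block the edgeR test also called 0 transcripts, and 499 had an unadjusted p under 0.05. Limma-voom called 0 transcripts. Its 613 transcripts at an unadjusted p under 0.05 went mostly the other way from edgeR's, with 434 higher and 179 lower in EV. DESeq2 without the block went the way of edgeR, with 278 higher and 517 lower. The block turned the balance in both of these tools, to 323 higher and 775 lower with limma-voom and 886 higher and 621 lower with DESeq2. It did not turn it in edgeR, with 194 higher and 305 lower. With the replicate block limma-voom called 24, of which 1 was higher and 23 were lower in EV.

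The median standard error of a log2 fold change was 1.06 over all tested transcripts. Among the 2909 transcripts with a mean log2 CPM of at least 5 it was 0.53. These are errors of single transcripts, and the adjustment for 18959 tests requires larger changes. On simulated counts with this spread the edgeR test recovered 0 of 48 transcripts changed 4-fold, 0 of 45 changed 8-fold and 4 of 39 changed 16-fold. In that simulation most changes of up to 16-fold were missed, and the count of 0 does not show that expression was equal.

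Of the transcripts tested, 856 were higher in all 3 EV libraries than in any PBS library and 779 were lower. Together these made up 8.62% of the tested transcripts, where chance gives 10% for 3 libraries against 3 that share nothing but their group. That value leaves out the pairing by replicate number. The other 3 splits of the libraries that part all same-numbered pairs gave 5.16%, 5.17% and 6.29%, all below the real split. They gave 296, 320 and 350 transcripts at an unadjusted edgeR p under 0.05, against 547 in the real split. With 4 such splits the share cannot fall under 0.25, and these splits were picked through a pairing read from the same libraries.

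The transcripts with the smallest p were counted in every library of one group and in none of the other. ENSDART00000165841.2 had 0 counts in each PBS library and 576, 436 and 505 counts in EV replicates 1, 2 and 3, or 30.8 ± 7.97 CPM (SD, n = 3). A count of 0 allows up to 3 counts per library, here 0.191 CPM in PBS, and the EV mean was 161-fold above this floor. Its adjusted p was 0.243 in the edgeR test, and from 6.51e-13 to 1 over 17 alternative settings, of which 4 passed the threshold. ENSDART00000151658.3 likewise had 0 counts in each PBS library and 318, 148 and 101 counts in the EV libraries, or 10.3 ± 2.52 CPM (SD, n = 3). The EV mean of this transcript was 53.8-fold above the PBS floor. Its edgeR adjusted p was 0.871, and 3 of 18 alternative settings passed the threshold. In the other direction, ENSDART00000003143.9 had 802, 165 and 407 counts in PBS replicates 1, 2 and 3, or 24.7 ± 11.6 CPM (SD, n = 3), and 0 in each EV library. The floor in EV was 0.187 CPM, and the PBS mean was 132-fold above it. The edgeR adjusted p of this transcript was 0.359, and 4 of 17 alternative settings passed the threshold. ENSDART00000151179.2 had 214, 69 and 104 counts in the PBS libraries, or 7.06 ± 1.94 CPM (SD, n = 3), and 0 in each EV library. Its PBS mean was 37.8-fold above the EV floor, with an edgeR adjusted p of 0.982 and 3 of 17 alternative settings past the threshold. Among the settings past the threshold is DESeq2 without the block, which also called unchanged transcripts in simulation; DESeq2 with the block was not simulated. The floors cover counting error only, and reads amplified without molecular identifiers are not independent molecules. They leave out the division of reads between similar transcripts. Each fold sets a group mean over a floor and leaves out the spread of that mean, so it is not a lower bound on the change. ENSDART00000151658.3 had 0 non-whole deposited values. ENSDART00000165841.2, ENSDART00000003143.9 and ENSDART00000151179.2 had 3, 2 and 3.

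**Figure D3:**
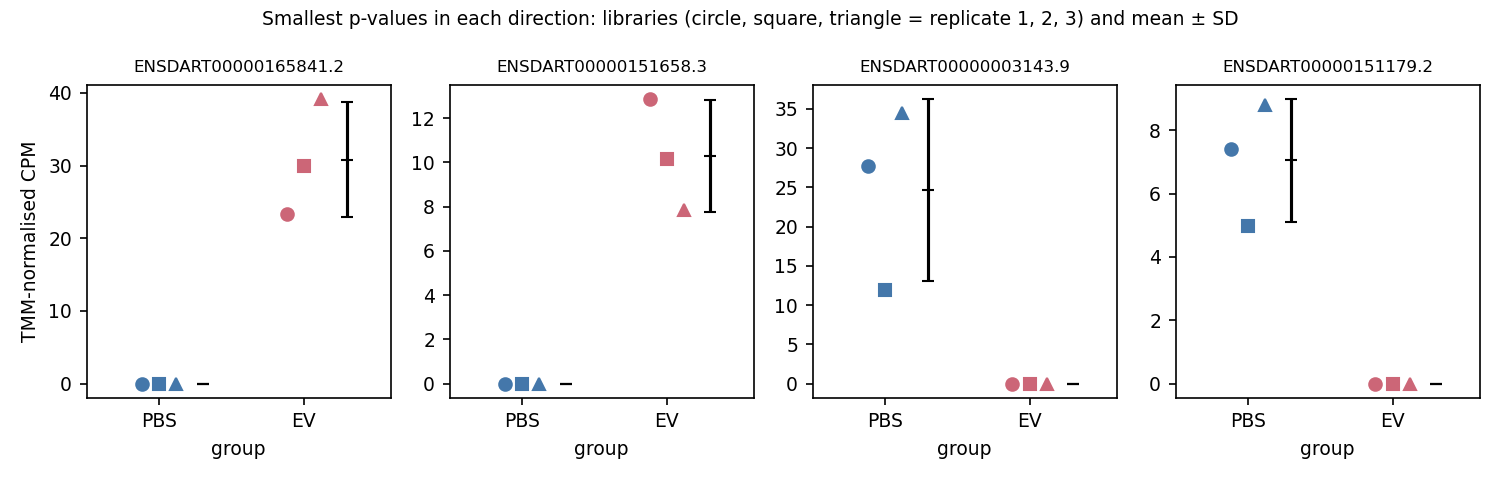
TMM-normalised CPM (vertical axes, linear, a separate scale per panel) of the 4 transcripts with the smallest p, by group (horizontal axes). Symbols are libraries and bars are mean ± SD of 3 libraries. The first pair of transcripts is at 0 in all PBS libraries and the second pair at 0 in all EV libraries.

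Over the whole table, 64 transcripts were at 0 in all 3 libraries of one group and at 10 or more counts in each library of the other. Of these, 40 were counted in EV alone and 24 in PBS alone. The DESeq2 Wald test called 62 of 18959 transcripts at an adjusted p of 0.05, with 29 higher and 33 lower in EV, and gave no adjusted p for 642. In simulated counts of independent libraries with this spread DESeq2 also called 85 of 16529 unchanged transcripts. That simulation leaves out the pairing by replicate number, which is an assumption. If the numbers mark pairs, the 85 is not a chance level for the 62. If they do not, the 62 calls do not exceed what the simulation gave for unchanged transcripts. Of all 10 splits into 3 and 3, 5 gave at least 62 DESeq2 calls, the real one included. The other 3 splits that part all same-numbered pairs gave 19, 21 and 27 DESeq2 calls, but their choice rests on the assumed pairing. Of the 62, 46 were at 0 in a whole group, 27 of them in all PBS libraries and 19 in all EV libraries. Of the other 16, 2 were higher in EV and 14 were lower, and all 14 had their highest share of counts in PBS replicate 3, the library that stood apart.

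The DESeq2 count changed when single libraries were left out, in fits added after seeing the data. Leaving out a library also changed the filter, so 20784 to 21652 transcripts were tested in place of 18959. The count was 248 without PBS replicate 1 (114 higher and 134 lower in EV). Without PBS replicate 2 it was 413 (244 higher and 169 lower), and without PBS replicate 3 it was 102 (70 higher and 32 lower). It was 74, 62 and 83 without EV replicate 1, 2 and 3, but these were in part different transcripts. Higher in EV were 24, 26 and 27 of them, and 50, 36 and 56 were lower. Of the 62 transcripts, 36 were called again in each of these 3 fits. Without PBS replicate 1, 2 and 3, 57, 60 and 41 of the 62 were called again, and 17 were called in each of the 6 fits that left out a library. With the replicate block DESeq2 called 164 transcripts, 67 higher and 97 lower in EV, which included 50 of the 62. Only 3 of the 62 were among the 24 called by limma-voom with the block.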

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

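The count of 0 changed transcripts held with edgeR under other size factors, library totals, a minimum of 10 counts in every library, robust estimation, thinning, an adjusted p of 0.1, a test against a 1.5-fold change, the replicate block (0 calls), and each of the 6 fits without 1 library. It also held with limma-voom, with or without sample quality weights. It did not hold without a filter on low counts, where edgeR called 427 of 39325 transcripts (94 higher and 333 lower in EV). Of these, 139 pass the main filter, 140 had counts in a single library and 283 of the 333 lower ones had most of their counts in PBS replicate 3; the cause was not tested. DESeq2 called 62. Among the alternatives chosen after seeing the data were DESeq2 with the replicate block (164 calls), limma-voom with the replicate block (24 calls) and edgeR on transcripts with whole values alone (0 calls among 3895); why the tools differ was not tested. The direction of the 4 transcripts named could not turn under any setting, since each is at 0 in a whole group. The within-group minus between-group correlation ranged from -0.0485 to 0.0621 when 1 library was left out, which also shifts the weight between the groups. The difference in transcripts detected at equal depth was 3610, and 1716 with a minimum of 10 counts; all alternatives for detection, correlations and library totals, their pairing by replicate number, and the DESeq2 fits without 1 library were also chosen after seeing the data. Tests of gene lists were not run under any setting, because no transcript could be tied to a gene with the reference tables used here. Depth is one limit, at 10393944 to 24332767 counts per library, and the spread between libraries, with a coefficient of variation of 93.3%, is another.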

Other observations

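The tests of depth, of lost transcripts and of non-whole values were set out before their results were seen; the counts over splits of the libraries, the removal of abundant transcripts and the restriction to values of at least 10 counts were chosen after.

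The real split gave 0 edgeR calls and the highest other split gave 4. All 10 splits necessarily reach a count of 0, so this comparison tests nothing. For DESeq2, 5 of the 10 splits gave at least the real count of 62, and the highest other gave 336. With 10 splits a share under 0.05 cannot be reached. The split with 336 calls set PBS replicate 1, EV replicate 1 and EV replicate 2 against the rest, and another with 274 set PBS replicate 1, PBS replicate 3 and EV replicate 3 against the rest. Counts several times the real one point to a structure of the samples other than the injection. Each of these splits keeps 2 same-numbered pairs of libraries together, as does every split that does not part all 3 pairs. The other splits of this kind gave 99, 131, 39 and 36 DESeq2 calls, so this trait alone did not give a high count. Every split with more than 62 calls was of this kind and kept PBS replicate 3 together with EV replicate 3. The splits with 39 and 36 calls parted these libraries. What these libraries share was not tested. Among the 4 splits that part all 3 pairs, the real one gave the most DESeq2 calls, 62 against 19, 21 and 27, and 4 splits are too few for a share under 0.05.

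Transcripts at 0 in a whole group and at 10 or more counts in each library of the other numbered 64, and 2 of the 10 splits gave as many, the highest other giving 96. Whether they arise from loss and gain of transcripts unrelated to the injection cannot be told apart from an effect of it, because 10 splits are too few; the other splits that part all pairs gave 31, 34 and 35. A candidate explanation for many of them is the division of reads between similar transcripts by the quantification. Among the 63 of them that were tested, 85.2% of the non-zero deposited values were not whole, against a median of 69.7% (95% of lists between 59.7% and 79.5%) in 10000 random lists matched on mean expression, and over values of at least 10 counts it was 85.2% against 60.2% to 79.7%. Such transcripts in the 9 other splits had shares between 83.3% and 94.8%, so the property is not tied to the injection, and an effect of EVs on transcript choice remains open and untested.

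PBS replicate 3 correlated less with the other libraries than any of them did, by a gap of 0.12 to the next lowest mean. The tables argue against sequencing depth as the cause, since the gap was 0.125 with all libraries thinned to the same total. They also argue against the complete loss of transcripts from this library, since the gap was 0.145 over the 10477 transcripts with at least 10 counts in all 6 libraries. Counts in PBS replicate 3 were concentrated, with 28.85% in its 10 most abundant transcripts against 13.01% to 19.09% in the other libraries. Of transcripts with at least 5 CPM in the other 5 libraries, 1.6% were at 0 in PBS replicate 3. The same share was 0.09% to 0.49% for the other libraries. Library complexity thus remains open and was not tested. A different mixture of cells in that sort also remains open, because it needs marker genes, and no biological explanation was tested.

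The higher number of transcripts detected in the EV libraries was not accounted for by a few abundant transcripts taking counts in PBS. With the 100 most abundant transcripts removed before thinning, the difference was 3399 ± 1265 (SE), and 3610 ± 1290 with them. Library complexity, the mixture of sorted cells and an effect of the injection remain open and untested.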
